A study of Mus musculus with 10 samples.

How the data were processed

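RNA was sequenced from 10 cultures of mouse dorsal root ganglion (DRG) neurons, the sensory neurons whose cell bodies lie beside the spinal cord. There were 5 replicate libraries from female and 5 from male C57BL/6J mice, a standard inbred strain. Per the labels' protocols, thoracic ganglia of 3-week-old mice were dissociated and cultured for 3 days in a medium with nerve growth factor, glial cell line-derived neurotrophic factor and AraC, which blocks DNA synthesis. The cells were then held for 60 min in 75 mM KCl, which depolarizes neurons, and lysed. The tissue label reads spinal cord, while the cell type label and the protocol name DRG neurons, and the latter are followed here. Ribosomal RNA was depleted, and libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols.

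The authors deposited 1 table of raw read counts per gene for each library. STAR 2.7.7a, the mm10 genome build, DESeq2 and edgeR are named per the submitters' processing notes, without the role of each. The counting program, the gene annotation and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands could not be told apart. Each table had 32719 gene rows, and mitochondrially encoded genes, 1 of the fixed lists, were not analysed here. Of the gene identifiers, 32663 matched GENCODE release M21 on the same mouse build, from which coordinates, exonic lengths and GC content were taken, and 56 did not match. Per the file footers, between 29355618 and 41423630 reads were available per library, of which 79.7% to 84.1% were assigned to genes and 15.9% to 20.3% were not. The footer lines name no gene and were left out of library sizes and tests. A further footer line for reads outside genes accumulates from library to library in 8 of the 10 files and was not used, and unassigned reads were taken as total minus assigned. Gene counts sum to 3.41% to 3.57% more than the assigned reads, so some reads were counted for more than 1 gene. The deposited counts were not altered.

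Counts were analysed in R 4.3.3. Genes were kept by edgeR 4.0.16's filterByExpr with sex as the group, which left 17316 genes. Library sizes were scaled by TMM, and sexes were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with sex as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Log2 fold changes are female minus male, and their standard errors (SE) are the log2 fold change divided by the square root of the quasi-likelihood F. CPM values (read counts scaled to a common library size with the TMM factors) are given as mean ± SD over 5 libraries, with Mthfs and the rod gene sums scaled by gene count sums without TMM factors. The replicates are separate samples per the labels, but nothing says that they came from separate animals, so p-values measure only the spread between these samples, which may be technical. Pairs of libraries of 1 sex differed by more than counting noise, with chi-square values per degree of freedom of 5.21 to 16.5 over genes with at least 20 counts, and all 10 were kept as separate.

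A total of 36 gene lists with 973 entries was fixed before the data were examined. They cover sex chromosome genes, insulin signalling and secretion, neuron subtypes, neuropeptides, activity and injury genes, the other cell types such cultures can hold, and housekeeping, stress and immune groups. Of the entries, 898 were tested. Lists with at least 5 tested members (34 lists) were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over lists. The mean log2 CPM of a list in each library was compared between the sexes by a two-sided exact permutation test over the 252 assignments of the 10 labels, whose smallest p is 0.00794. Counts of called members are given over all genes tested and adjusted over the list alone, and where the second is not given it equals the first. In each list where edgeR called 0 members limma-voom also called 0, and the number called by DESeq2 is given beside it.

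Named genes followed a rule fixed at the same time. It took the 4 called members with the smallest p of each of the 2 sex chromosome lists. Outside these lists it took 12 genes per direction with the largest fold change among those called, with a mean log2 CPM of at least 1 and no overlap between the sexes, leaving out symbols that begin with Gm and a digit or end in Rik. From each list it took up to 4 tested members with the smallest p, called or not. Of the 158 genes taken, 44 share exonic bases with another annotated gene, 5 of them over more than 20% of their exonic length (H1f4, Hist1h2ao, Hsd3b7, Igf2 and Kif20a).

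The procedure was tested on simulated data, a table of 17171 genes drawn from the means and depths of these libraries with 200 changed genes. For a female to male difference of 0.3 on the log2 scale 40.3% of changed genes were recovered, for 0.5 it was 79.4% and for 1 it was 98.6%, and 8 unchanged genes stood among 154 called. Genes were drawn independently, so shifts shared by many genes of a library were not simulated. These rates may therefore not hold for the deposited data. With a simulated length trend of 0.15 (log2 per SD of log2 exonic length) in the females, 1153 unchanged genes were called without an offset for length and 5 with it, and the slope in the deposited data was 0.04. The simulated trend was the same in each female library, whereas the female libraries of the deposited data differed in theirs. Alternatives were other normalizations (RLE and upper quartile), DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in at least 5 libraries, robust estimation, the replicate number as a block, 1 surrogate variable from sva 3.50.0 and leaving out each library in turn. Chosen after seeing the data were a per-library offset for exonic length and GC content (splines with 4 degrees of freedom) and a fit without female libraries 4 and 5. The proteins secreted by these cultures were not analysed here.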

Results

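The data comprised RNA-seq counts from 5 female and 5 male libraries of depolarized mouse DRG neuron cultures. Gene counts summed to between 24894851 and 27467183 in female libraries 1 to 4 and to 36020193 in female library 5. The male libraries held 25393316 to 32033878 counts. The single comparison was between the sexes, and by its title the study asked whether sensory neurons of females and males differ in pathways tied to insulin sensitivity and insulin secretion.

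The sex-linked genes matched the labels in all 10 libraries. Xist, the non-coding RNA that silences an X chromosome (chromosome X, 103460366 to 103483254, mm10), stood at 1531 ± 126 CPM in females and 33.0 ± 3.85 CPM in males (SD, n = 5 each), a level of 2.2% of the female mean. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had 1030 to 2870 counts in each male library and 2 to 30 in each female library. Their log2 fold changes lay between -7.78 and -7.12. Of 13 tested X-linked genes known to escape inactivation or silence the X, 8 were higher in females and 0 in males, with 9 and 1 adjusted over the list alone. The number called was 5 without female library 3 or 4, 6 to 8 without any other 1 library, and 6 after an offset for length and GC content. Among the 8 were the translation initiation factor gene Eif2s3x (1.63-fold, log2 0.70 ± 0.04 SE), and the histone demethylase genes Kdm6a (1.61-fold, log2 0.68 ± 0.05) and Kdm5c (1.39-fold, log2 0.48 ± 0.04). Before that offset this list was the only 1 of 34 that passed camera with an estimated correlation (adjusted p = 0.00324). After the offset, chosen after seeing the data, its adjusted p was 0.03, and the endothelial and mural markers also passed (0.0402).

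Beyond the sex chromosomes, genes of blood vessel endothelium were higher in the female cultures. Endomucin, Emcn, a sialomucin of capillary and venous endothelium (chromosome 3, 137341067 to 137432185), stood at 16.2 ± 0.258 CPM in females and 10.1 ± 0.746 in males, which is 1.61-fold (log2 0.68 ± 0.07 SE, adjusted p = 4.99e-05, edgeR). The VEGF receptor genes Kdr and Flt1 were 1.62-fold and 1.55-fold higher, and the endothelial adhesion genes Pecam1 and Cdh5 were 1.47-fold and 1.46-fold higher. Sox18, a transcription factor of vascular development, and Adgrf5, an adhesion G protein-coupled receptor, were 1.57-fold and 1.51-fold higher. Of 22 tested endothelial and mural cell markers 7 rose in females and 0 in males, with 12 and 0 adjusted over the list alone, and the median log2 fold change was 0.32. The 7 members called by edgeR are all endothelial (Emcn, Cdh5, Pecam1, Kdr, Flt1, Vwf and Tie1), and edgeR called 0 of 10 mural markers. DESeq2 called 11 members of the list. The list passed camera (adjusted p = 7.56e-08), but its adjusted p was 0.078 with an estimated correlation, and its level separated the sexes with an exact permutation p of 0.00794, the smallest possible, which was 0.0556 after adjustment over lists.

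**Figure D1:**
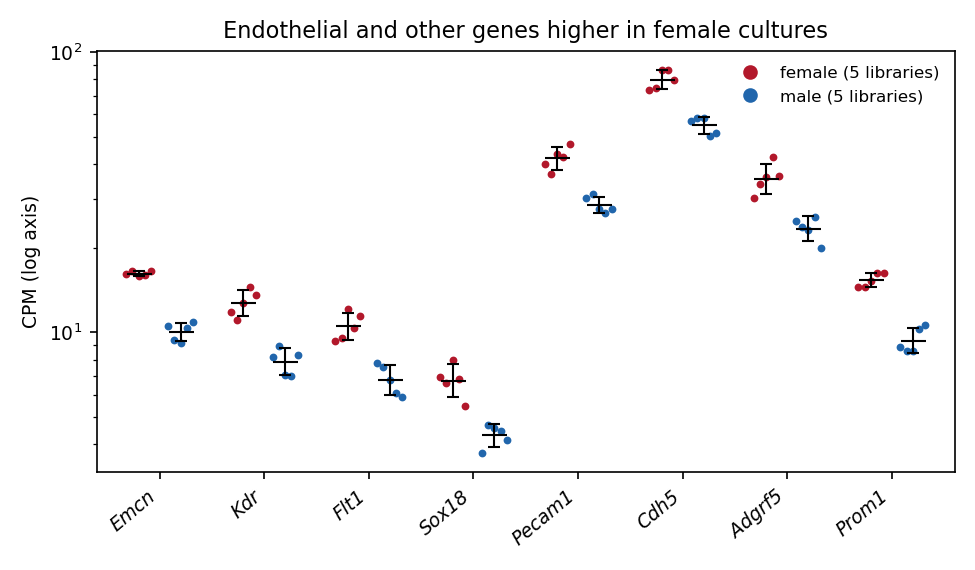
CPM (log axis) of 8 genes in each of the 5 female and 5 male libraries, with black marks for the mean and SD on the log scale. Each gene has higher values in all 5 female than in all 5 male libraries, for example 16.2 against 10.1 CPM on average for Emcn. For Emcn, Kdr, Flt1, Sox18, Adgrf5 and Prom1 this absence of overlap was a condition of the naming rule and is no separate result.

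In total 441 of 17316 genes differed (edgeR, adjusted p under 0.05), 327 of them higher in females and 114 in males, and 429 lay outside the 2 sex chromosome lists. Of the called genes 15 on the X were higher in females, 3 on the X and 5 on the Y were higher in males, and 418 were autosomal. Changes were small: the median absolute log2 fold change of the 429 was 0.32, and 54 of them reached 1.5-fold. An unadjusted p under 0.05 (edgeR) was reached by 3891 of the 17316 tested genes, the share to set beside such counts in the lists below. The 5 female and 5 male values did not overlap for 345 of the called genes and for 968 of all tested genes, where chance gives 0.794% of genes. With upper-quartile scaling the split was 230 to 164, against 327 to 114 with TMM. The count moved by more than 1.5 times when any library except male 4 was left out, from 50 without female 4 to 868 without female 1. It was 87 without female libraries 4 and 5, with 49 of these among the 441. Genes with a longer total exonic length were on average higher in the female libraries. Spearman's rho of log2 fold change with exonic length was 0.31 across 13687 genes, which are not independent replicates. After an offset for length and GC content 285 genes were called. Per library, the correlation of expression deviations with log2 exonic length averaged 0.093 in females and -0.108 in males. The exact permutation p was 0.0397, or 0.111 adjusted over the library measures. Female libraries ranged from -0.121 (library 1) to 0.247 (library 5).

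**Figure D2:**
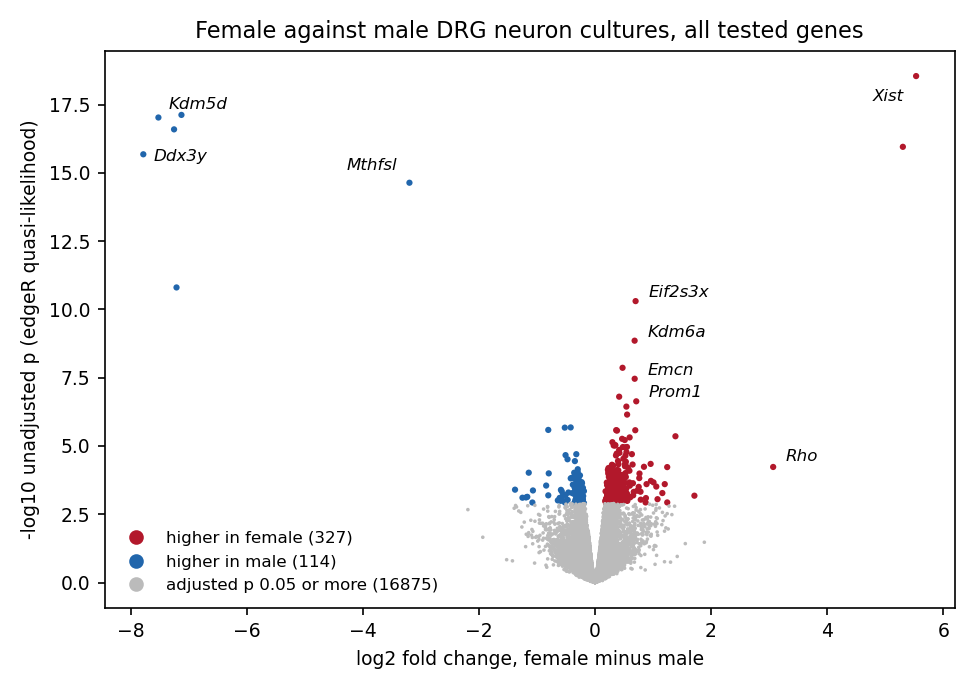
Log2 fold change, female minus male, against -log10 of the unadjusted p for each tested gene. Red points are the 327 genes higher in females, blue points the 114 higher in males, and grey points did not pass an adjusted p of 0.05. Xist, the Y-linked genes, Mthfsl and Rho lie farthest from 0 among the labelled genes.

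Rho, the gene of the rod photopigment rhodopsin (chromosome 6, 115931748 to 115940036), had the largest autosomal rise among the named genes, at 46.4 ± 47.9 CPM in females and 5.42 ± 3.05 in males (8.40-fold, log2 3.07 ± 0.56 SE, adjusted p = 0.0177, edgeR). Female library 4 alone held 130 CPM, and the other 4 female libraries held 19.2 to 44.0. Without female library 4 Rho was 4.64-fold higher in females. The zinc finger gene Zfp366 was 1.94-fold higher in females, the transcription factor gene Mecom 1.70-fold, and Prom1, which encodes the membrane glycoprotein prominin 1, 1.64-fold. The remaining named genes higher in females were Cyyr1, the small nucleolar RNA gene Snora17 and the microRNA host gene Mir17hg, at 1.57-fold to 1.80-fold. Mir17hg lost its call in 7 of 21 alternatives, Mecom in 5, Cyyr1 in 4, Zfp366 in 2, Rho and Snora17 in 1 each, and Prom1 in 0.

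Mthfsl, a gene related to the folate enzyme gene Mthfs (chromosome 9, 88688602 to 88720296), was 9.17-fold higher in males, at 44.7 ± 2.47 CPM against 4.83 ± 0.901 CPM (log2 -3.20 ± 0.10 SE, adjusted p = 5.68e-12, edgeR). Its paralog Mthfs stood at 4.25 ± 0.657 CPM in females and 4.61 ± 0.616 in males. The olfactory receptor gene Olfr32 was 2.21-fold higher in males at a low level (3.05 against 1.39 CPM). Pou4f3, a POU-domain transcription factor gene of sensory neurons and hair cells, was 1.52-fold higher, and Rom1, an outer segment membrane protein gene, 1.5-fold. Hcrtr2, the orexin receptor 2 gene, and Chrm4, the muscarinic receptor M4 gene, were 1.46-fold and 1.43-fold higher in males. Both stood at low levels, Hcrtr2 at 2.79 CPM in females and 4.10 in males, and Chrm4 at 2.84 and 4.06. The histone gene Hist1h2ao (1.43-fold), Slitrk3, Cst6, Cilp2 and the microRNA genes Mir1983 and Mir7688 complete the 12. Under the length and GC offset the adjusted p of Pou4f3, Rom1, Cilp2 and Chrm4 rose to between 0.0615 and 0.0908, though most of the fold stayed. Their log2 fold changes went from -0.608 ± 0.145 SE to -0.562 ± 0.146, from -0.589 ± 0.145 to -0.499 ± 0.151, from -0.578 ± 0.141 to -0.524 ± 0.145 and from -0.514 ± 0.127 to -0.430 ± 0.125. Cilp2 lost its call in 13 of 21 alternatives, Rom1 and Chrm4 in 12 each, and Pou4f3 and Mir7688 in 10 each. Hcrtr2 and Slitrk3 lost theirs in 9 each, Olfr32 in 4, Cst6 in 1, and Mthfsl, Mir1983 and Hist1h2ao in 0.

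**Figure D3:**
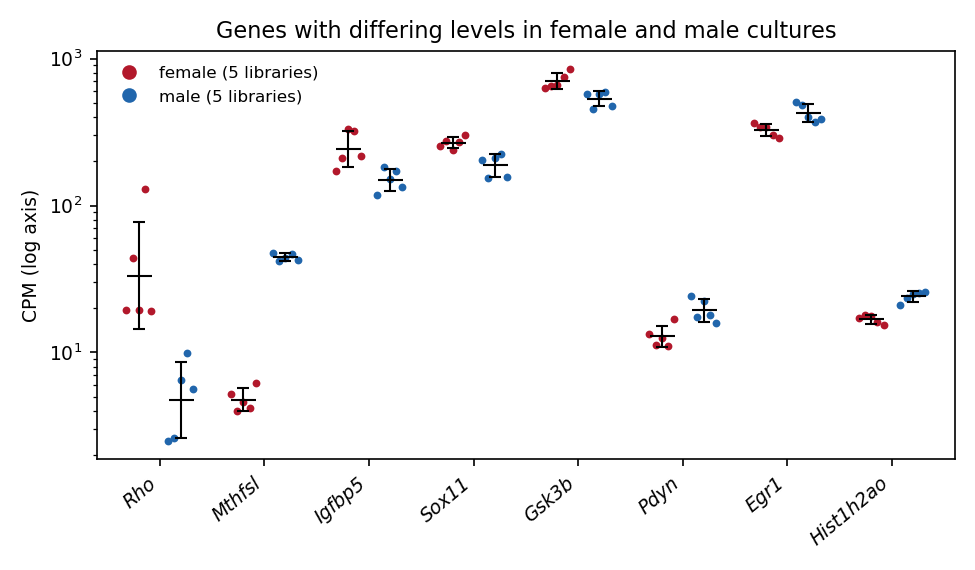
CPM (log axis) of 8 called genes per library, with black marks for the mean and SD on the log scale over 5 female (red) and 5 male (blue) libraries. Rho spreads from 19.2 to 130 CPM among the females, whereas Mthfsl lies near 44.7 CPM in the males and near 4.83 CPM in the females.

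Genes of insulin signalling, the cascade downstream of the insulin receptor, had slightly higher levels in females. Of 43 tested members 4 rose in females and 0 in males (7 and 0 adjusted over the list alone), and 31 had a positive log2 fold change, with a median of 0.09. The 4 were Foxo1, a transcription factor restrained by insulin (1.39-fold, log2 0.48 ± 0.10 SE), Gsk3b, a kinase that restrains glycogen synthesis (1.32-fold, 0.40 ± 0.09), and the PI3-kinase subunit genes Pik3r1 (1.29-fold, 0.36 ± 0.08) and Pik3ca (1.17-fold, 0.23 ± 0.05). The list passed camera (adjusted p = 3.11e-04), with an adjusted p of 0.579 with an estimated correlation. After the length and GC offset the median was 0.05 and 1 member was called. List levels were highest in female libraries 4 and 5 (6.070 and 6.028 log2 CPM). Female library 1 (5.949) lay just above the highest male level (5.941). The number of called members was 6, 1, 0, 0 and 0 without female libraries 1 to 5 and 1, 1, 0, 2 and 0 without male libraries 1 to 5, and the 4 genes lost their call in 8 to 11 of 21 alternatives each.

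Genes of insulin secretion and regulated exocytosis did not pass the list test. Of 51 tested members only Adra2a, the alpha-2A adrenergic receptor gene, was called by edgeR (3 by DESeq2), at 29.9 ± 4.23 CPM in females and 19.7 ± 4.17 in males (1.52-fold, adjusted p = 0.0327, edgeR). Adjusted over the list alone, 2 members were higher in females, and the median log2 fold change was 0.03 (camera adjusted p = 0.744). Among 33 metabolic hormones, adipokines and growth factors only Igfbp5, which encodes an IGF-binding protein, was called by edgeR (4 by DESeq2), at 1.65-fold higher in females (log2 0.73 ± 0.16), with 2 higher in each sex adjusted over the list alone. Among 27 neuropeptides and granins only Pdyn, the prodynorphin gene, was called by edgeR (4 by DESeq2), at 1.5-fold higher in males (log2 -0.59 ± 0.13), with 0 and 4 adjusted over the list alone. The granin genes Chgb and Chga had log2 fold changes of -0.33 ± 0.09 and -0.28 ± 0.08 and were not called by edgeR, but passed in 5 and 3 of 21 alternatives. Of 26 genes of glycolysis and glucose uptake 0 were called over all genes tested by edgeR and 2 by DESeq2, 5 had an unadjusted p under 0.05, and Pfkfb3, which encodes a regulator of glycolysis, was higher in females adjusted over the list alone. Leaving out 1 library gave 0 to 3 called members for secretion, 0 to 2 for hormones and 0 to 5 for neuropeptides. Adra2a lost its call in 8 of 21 alternatives, and Igfbp5 and Pdyn in 7 each.

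Lists of genes for DNA packaging and for protein and energy production had lower median levels in females. Of 25 tested replication-dependent histone genes 9 were lower in females and 0 higher (23 and 0 adjusted over the list alone), with a median log2 fold change of -0.29. H3c2 stood at 89.6 ± 9.55 CPM in females and 113 ± 6.5 in males (1.27-fold, log2 -0.34 ± 0.07 SE), and H1f4 at 247 ± 29.3 and 307 ± 14 CPM (1.24-fold). These genes exist in many similar copies, so the split of reads between them is uncertain. The number called was 19, 9, 0, 0 and 5 without female libraries 1 to 5 and 6, 0, 1, 5 and 0 without male libraries 1 to 5. All 50 cytosolic ribosomal protein genes had negative values (median -0.16), of which 0 were called by edgeR over all genes tested, 9 by DESeq2 and 23 adjusted over the list alone, and 34 had an unadjusted p under 0.05. The mean ribosomal level was lowest in female libraries 5 and 4 (7.006 and 7.098 log2 CPM). These 2 libraries had the most positive correlation with log2 exonic length (0.247 and 0.229). Female library 1 (7.355) lay within the male range (7.322 to 7.394). The highest ribosomal level was that of male library 3, whose correlation was the most negative (-0.230). Female libraries 5, 4 and 3, the lowest for the ribosomal and histone lists, also had the lowest share of Malat1 counts (0.430%, 0.472% and 0.502%). Of 45 nuclear genes of oxidative phosphorylation 42 were negative, with a median of -0.11 that became -0.04 after the length and GC offset. Of these 45 genes 0 were called by edgeR, over all genes or adjusted over the list alone, 6 by DESeq2 and 19 at an unadjusted p under 0.05. Among 30 cell cycle genes Tyms, the thymidylate synthase gene, was called (1.20-fold higher in males, 0 to 2 called members when 1 library was left out), 8 were higher in males adjusted over the list alone, and the median was -0.12. These 4 lists and the 33 proteasome subunits (median -0.06, 0 called by edgeR, 2 by DESeq2, 5 at an unadjusted p under 0.05) passed camera at adjusted p of 2.41e-13 for histones, 6.11e-13 for ribosomal proteins, 4.52e-07 for oxidative phosphorylation, 2.24e-05 for the cell cycle and 0.00244 for the proteasome. With an estimated correlation the adjusted p was 0.579 for histones and 0.942 for the other 4, and 52 of 100 splits of the 10 libraries into 5 and 5 gave at least the 10 lists that passed camera by sex.

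**Figure D4:**
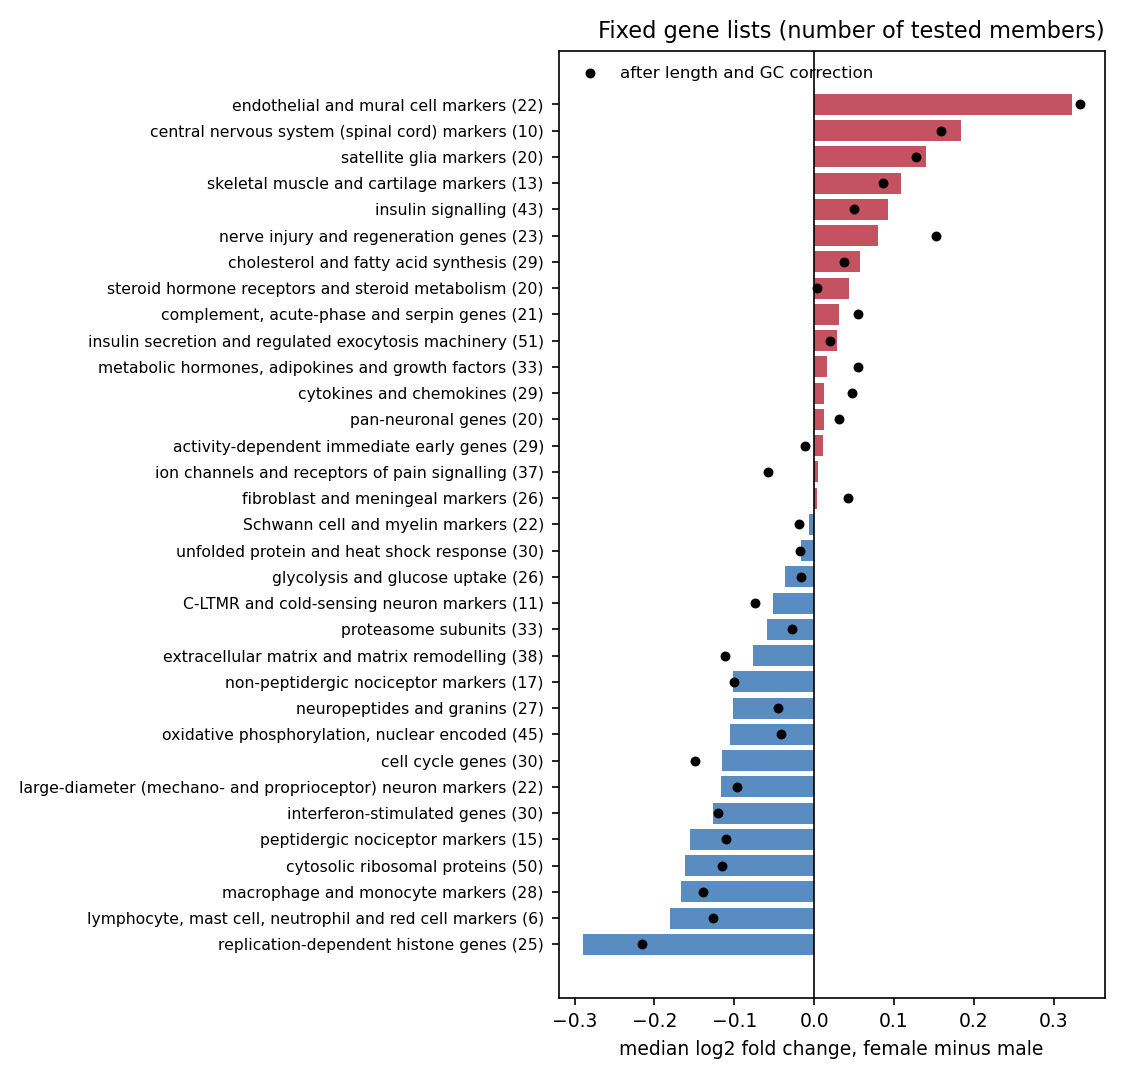
Median log2 fold change, female minus male, of the tested members of each list with at least 5 of them, leaving out the X-linked list. Bars are the values without correction and black points those after the length and GC offset, for example 0.32 and 0.33 for endothelial and mural markers and -0.29 and -0.22 for histone genes.

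Few neuronal markers were called over all genes tested by edgeR. Of 20 pan-neuronal genes only the RNA-binding protein gene Elavl3 was called (1.25-fold higher in females). Among the subtype lists, 0 of 17 non-peptidergic nociceptor markers and 0 of 11 C-LTMR and cold-sensing markers were called by edgeR, with 1 each by DESeq2 and 5 and 3 at an unadjusted p under 0.05. Adjusted over the list alone, 1 non-peptidergic marker was lower in females. Adra2a was the called gene among 15 peptidergic nociceptor markers, and Lgi2 (1.31-fold higher in females) among 22 markers of large-diameter neurons. Of the peptidergic markers 10 had an unadjusted p under 0.05, and adjusted over the list alone 2 were higher and 5 lower in females. Of the large-diameter markers 6 had an unadjusted p under 0.05, and 3 were higher and 1 lower adjusted over the list alone. The itch receptor gene Mrgprx1 had 2.44 ± 0.693 CPM in females and 4.32 ± 1.09 in males and was not called (adjusted p = 0.0546, edgeR), but passed in 5 of 21 alternatives. Calca, the CGRP gene, had a log2 fold change of -0.20 ± 0.06 and was not called by edgeR, but passed in 3 of 21 alternatives. Of 37 ion channels and receptors of pain signalling 0 were called by edgeR and 3 by DESeq2, with a median of 0.01. At an unadjusted p under 0.05 there were 12, against 3891 of all 17316 tested genes. Among 29 activity-dependent immediate early genes 2 were lower in females, Egr1 (327 ± 32.2 against 429 ± 60.2 CPM, 1.31-fold) and Ier2 (1.29-fold), and with adjustment over the list alone 3 were higher and 2 lower. Of 23 nerve injury and regeneration genes the transcription factor genes Sox11 (1.41-fold) and Smad1 (1.29-fold) were higher in females, and adjusted over the list alone 3 were higher and 1 lower. That list passed camera (adjusted p = 0.025), with an adjusted p of 0.942 with an estimated correlation and of over 0.05 (up to 0.118) without female library 1 or 2 or male library 2 or 5. Male libraries 2 and 5 had the lowest injury list levels (6.872 and 6.870 log2 CPM) and the other 3 males lay within the female range (7.091 to 7.180). In the lists of this paragraph with 1 or 2 called members, leaving out 1 library gave 0 to 4. Over the 21 alternatives Ier2 lost its call in 10, Egr1 and Lgi2 in 9 each, Adra2a in 8, Elavl3 in 4, Sox11 in 3 and Smad1 in 1.

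Among the other cell types that such cultures can hold, few markers were called. No member of the satellite glia (20), Schwann cell and myelin (22), macrophage and monocyte (28), or lymphocyte, mast cell, neutrophil and red cell (6) lists was called by edgeR over all genes tested, with 6, 6, 1 and 0 members at an unadjusted p under 0.05. DESeq2 called 2 satellite glia genes, each higher in males, and 0 in the other 3 lists. Adjusted over the list alone, 4 satellite glia markers were higher and 2 lower in females. The satellite glia potassium channel gene Kcnj10 had a log2 fold change of 0.59 ± 0.19 and was not called by edgeR, but passed in 2 of 21 alternatives. Apoe, Sparc and Sox10 of that list passed in 5, 1 and 1. The satellite glia list had a median of 0.14 and an adjusted p of 0.0987 by camera, which it passed in 4 of 17 alternatives. Of 26 fibroblast and meningeal markers the chemokine gene Cxcl12 was called (1.40-fold higher in females, 0 to 3 called members when 1 library was left out), and adjusted over the list alone 2 were higher and 1 lower. Mean macrophage marker levels differed between libraries of 1 sex, from 1.64 log2 CPM in female library 5 to 2.87 in female library 2, and from 1.94 in male library 5 to 3.33 in male library 4. The 10 tested spinal cord markers and the 13 of muscle and cartilage held 0 genes called by edgeR, each with 3 at an unadjusted p under 0.05, and DESeq2 called 1 and 2. Adjusted over the list alone, 1 spinal cord marker was higher in females, and of muscle and cartilage 1 was higher and 1 lower.

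Among 38 extracellular matrix genes 4 were higher in females (Adamts1, Spon1, Col12a1 and Tnr) and Lama2, a laminin chain gene, was lower (1.23-fold), while adjustment over the list alone gave 4 and 7. These 5 called genes became 8, 1, 1, 1 and 1 without female libraries 1 to 5 and 1, 3, 2, 3 and 2 without male libraries 1 to 5. Of 21 complement, acute-phase and serpin genes Cfh, which encodes complement factor H, was higher in females (1.32-fold) and Serpina3g lower (1.26-fold), with 3 and 1 adjusted over the list alone. After the length and GC offset 0 of them were called, with log2 fold changes of 0.345 ± 0.099 for Cfh and -0.291 ± 0.088 for Serpina3g. Cxcl12 was the called gene among 29 cytokines and chemokines. Leaving out 1 library gave 0 to 3 called complement genes and 0 or 1 called cytokine genes. The 30 interferon-stimulated genes held 0 genes called by edgeR (1 by DESeq2, 3 at an unadjusted p under 0.05) and had a median of -0.13 (camera adjusted p = 0.025, and 0.955 with an estimated correlation). The camera p was 0.0966 to 0.355 without female library 1, 3 or 4 or male library 1, 2 or 3, and female libraries 3 and 4 had the lowest levels (3.933 and 3.868 log2 CPM), with the other females (4.179 to 4.497) within the male range (4.027 to 4.593). In the lists of steroid receptors and metabolism (20), cholesterol and fatty acid synthesis (29), and the unfolded protein and heat shock response (30), 0 genes were called by edgeR, with 0, 10 and 7 at an unadjusted p under 0.05 and 0, 1 and 3 called by DESeq2.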

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

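Tests of cell type shares, of rod genes and of the Mthfs paralog were chosen only after the results were seen, and bounds on list medians after the length and GC offset were written down before their values were known. A library far from the other 4 of its sex was looked for in 392 groups of values, and 20 (5.1%) were found by Dixon's test, where chance gives about 1 in 20.

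Female library 5 was the deepest, with 36020193 counts against 24894851 to 27467183 in the other female libraries, and it held 6 of the 20 deviating values. Besides depth, these were 149 CPM of Kdm5c (others 161 to 165), 97.3 CPM of Ndufa4 (104 to 106), 0.739 CPM of Mrgpra3 (0.243 to 0.346), 9.15 CPM of Slc1a2 (6.88 to 7.53) and 0.966 CPM of Gad2 (1.54 to 1.74). Female library 4 stood apart by 130 CPM of Rho, female library 1 by 2.19 CPM of Olfr32 (others 1.11 to 1.29), female library 2 by 3.47 CPM of Chrm4 (2.60 to 2.73) and female library 3 by a mean of 3.27 log2 CPM over the non-peptidergic nociceptor markers (3.43 to 3.46).

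Among the males, library 3 was low for the Y-linked genes Uty (39.9 CPM, others 49.4 to 52.9) and Kdm5d (38.6 CPM, others 47.7 to 51.2) and for Zfp366 (1.16 CPM, others 1.77 to 1.96). Male library 2 was high for the matrix list (7.46 log2 CPM, others 7.21 to 7.28) and for Fbln2 (592 CPM, others 462 to 487), and low for Ndufs8 (24.7 CPM, others 28.9 to 29.7). Male library 4 had -0.00339 log2 CPM over the lymphocyte, mast cell, neutrophil and red cell markers (others -0.811 to -0.631) and 12 CPM of Csf1r (others 10.5 to 10.6). Male library 5 had 4.21 log2 CPM over the steroid list (others 4.04 to 4.09) and 487 CPM of H3c6 (others 457 to 463).

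Rho and Mthfsl, each over 8-fold apart between the sexes on autosomes (4.64-fold for Rho without female library 4), are single-gene patterns with a technical candidate each. Retinal rod RNA in the female libraries would bring other abundant rod transcripts, but 13 other rod genes summed to 5.24 CPM in females and 5.60 in males, a ratio of 0.936, against 45.9 CPM of Rho in females on that scale (without TMM factors), which argues against it. Reads shared with the paralog Mthfs would need a matching loss there, but Mthfsl was 39.8 CPM higher in males while Mthfs held 4.25 CPM in females and 4.61 in males. A difference of sex in the expression of either gene stays open and was not tested further, as does a similar sequence elsewhere in the genome, since no genome sequence was searched.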

How the results depend on the processing

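Only the length and GC offset and the fit without female libraries 4 and 5 were added after seeing the data. Of 3306 values of named genes under alternatives 0 changed direction where a call was involved, 2861 kept their side of the threshold, 291 fell below it and 154 rose past it. Of the 59 named genes called, 18 passed under every alternative run, namely 8 sex-linked genes, Emcn, Kdr, Cdh5, Pecam1, Adgrf5, Prom1, Adamts1, Mthfsl, Mir1983 and Hist1h2ao. Where a cause is not given, it was not tested.

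The number of genes differing (441, with 327 higher in females, 114 in males and 429 outside the sex chromosome lists) became 1337 (860, 477 and 1325) with DESeq2, 285 (180, 105 and 275) with the length and GC offset, and 87 (72, 15 and 77) without female libraries 4 and 5, which also has fewer samples. Of these 1337, 285 and 87 genes, 436, 242 and 49 were among the 441, so the genes called changed as well as their number. Without the filter 180 genes were higher in males. Leaving out 1 library gave 50 to 868 genes differing, 35 to 563 higher in females, 15 to 305 higher in males and 41 to 856 outside the lists. The counts were 868, 190, 84, 50 and 283 without female libraries 1 to 5, and 232, 159, 111, 340 and 82 without male libraries 1 to 5. Upper-quartile scaling called 394 genes, 58.4% of them higher in females against 74.1% with TMM. RLE, limma-voom, the stricter filter, robust estimation and 1 surrogate variable gave 401 to 501 genes. The number of lists passing camera (10) was 1 with an estimated correlation, 4 by fry and 8 to 11 without 1 library. The histone list had 9 called members, 19 without female library 1 and 0 without female library 3 or 4 or male library 2 or 5, while the endothelial and mural list had 7, with 6 to 8 when 1 library was left out.

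The replicate block gave 585 genes (418 higher in females, 167 in males, 573 outside the lists), of which 350 were among the 441. Whether the replicate numbers mark shared preparations stays open. Same-numbered libraries correlated at 0.04, -0.01, -0.01, 0.09 and 0.12 in their deviations from the group means, and only female library 5 correlated best with its own number. Differences of 0.3 on the log2 scale were at the edge of what 5 libraries per sex detect, with 40.3% of such genes recovered in simulated data, where genes were drawn independently.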

Other observations

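The tests of cell type shares, of list levels after the length and GC offset and of the fit without female libraries 4 and 5 were chosen only after the results were seen. The single genes of this and the next paragraph were picked after their values were seen and stand for no group, since 0 of the 10 mural markers on the fixed list were called by edgeR and the endothelial gene Egfl7 was at -0.08. Ptprb, an endothelial phosphatase gene, stood at 18.6 ± 2.55 CPM in females and 12.7 ± 0.482 in males (log2 0.55 ± 0.09 SE). Plvap, of fenestrated endothelium, had a log2 fold change of 0.42 ± 0.07, Eng, a co-receptor gene of TGF-beta, one of 0.40 ± 0.08, and Abcb1a, an efflux pump gene of the blood-brain barrier, one of 0.53 ± 0.08. The transcription factor genes Fli1 (0.59 ± 0.11) and Epas1 (0.41 ± 0.07) were also higher in females.

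Of the fixed cell cycle list 1 of 30 genes was called by edgeR, and its adjusted p was 0.942 with an estimated correlation. Outside it, Pola2, a subunit gene of DNA polymerase alpha, stood at 22.7 ± 0.945 CPM in females and 30.3 ± 1.81 in males (log2 -0.42 ± 0.06 SE). Ndc80, of the kinetochore, had a log2 fold change of -0.32 ± 0.05, Rad51ap1, of DNA repair, one of -0.35 ± 0.06, and Spag5, of the mitotic spindle, one of -0.30 ± 0.05.

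Whether chance could give such counts was tested on 100 splits of the 10 libraries into 5 and 5. The counts weighed were 441 genes differing, 327 higher in females, 114 higher in males and 429 outside the sex chromosome lists. For each, only the split by sex (1 of 100) gave as many, and the highest other split gave 32. These values argue against a random grouping of the libraries. The other splits mix the sexes, which can widen the spread within a side. A preparation that differed with sex cannot be told apart from sex by these splits. For the 10 lists passing camera, 52 of 100 splits, the split by sex included, gave at least as many. The other splits had a median of 10 lists and a highest of 19. The number by sex was thus no larger than is usual for mixed groupings, and chance is not excluded for it.

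For the endothelial genes higher in females, the median log2 fold change of the list was 0.333 after the length and GC offset and 0.323 before it, which argues against a length or GC trend. A lower share of neurons would raise all other cell types alike, but the endothelial and mural level rose by 0.282 ± 0.115 SE (log2) relative to the mean of the satellite glia, Schwann cell, fibroblast and macrophage lists (exact permutation p = 0.0238), and that mean differed by 0.012 ± 0.098. A larger share of endothelial cells in the female cultures is a candidate explanation: 11 of 12 endothelial markers lay above 0, and the 5 that were not called had a median of 0.335. Whether such a share would come from the sex of the animals or from dissection was not tested, and higher expression per endothelial cell stays open too.

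The lists that moved with gene length were weighed as a group, that is histone, ribosomal protein and oxidative phosphorylation genes (higher in males) and insulin signalling genes (higher in females). The offset took rho with exonic length from 0.308 to 0.015. Beforehand a list's median after it was to stay below -0.19 (histone genes), below -0.11 (ribosomal proteins) or above 0.06 (insulin signalling) to speak against the trend. The histone median was -0.215 (from -0.289) and the ribosomal one -0.115 (from -0.162), past their bounds by less than the SE of the level, and the insulin one was 0.050 (from 0.093), short of its bound. List levels after the offset differed by -0.214 ± 0.050 SE for histone genes and 0.073 ± 0.018 for insulin signalling (exact permutation p = 0.00794 each, the smallest possible). Without female libraries 4 and 5 they differed by -0.141 ± 0.030 and 0.049 ± 0.014 (exact permutation p = 0.0179 each, again the smallest possible). By this level test, chosen after the results were seen, part of each difference stayed beyond the trend as the offset models it. By the bound set beforehand, the insulin median did not speak against the trend. In the fit without female libraries 4 and 5 and without the offset, which has fewer samples, 0 members of either list were called. These lists were taken up because they differed between the sexes, which weakens this support. After the offset, camera with an estimated correlation gave an adjusted p of 0.268 for each of them. Called members went from 9 to 4 and from 4 to 1, for instance Gsk3b from 0.403 ± 0.089 SE to 0.332 ± 0.082. In all 8 members that lost their call both the fold and its SE shrank and the unadjusted p rose, for Gsk3b from 4.19e-04 to 0.00113 (edgeR). For 5 of them the unadjusted p would still have passed at the limit that held before the offset (0.00127, against 8.21e-04 after it). For ribosomal proteins the level after the offset differed by -0.116 ± 0.045 (exact permutation p = 0.0238), but by -0.050 ± 0.026 (exact permutation p = 0.0536) without these 2 libraries, so the trend and a difference between the sexes cannot be told apart there. Oxidative phosphorylation went from a median of -0.105 to -0.041, as the trend would give. Its level differed by -0.104 before the offset and by -0.061 ± 0.031 after it (exact permutation p = 0.0873). Without female libraries 4 and 5 that was -0.033 ± 0.037 (exact permutation p = 0.339). After the offset the list still passed camera (adjusted p = 0.00205, and 0.921 with an estimated correlation), so a remaining difference is not settled. A larger share of dividing cells in male cultures may add to the histone difference: histone minus cell cycle level differed by -0.165 ± 0.105 (exact permutation p = 0.167), which is too wide to decide.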
